A study of Homo sapiens with 18 samples.

How the data were processed

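Gene expression was measured in MCF10A, an established human mammary epithelial line that does not form tumours, with 18 Affymetrix whole-transcript arrays in 6 groups of 3. Per the labels' protocols, cells were infected at a multiplicity of 5 with lentivirus carrying a non-targeting hairpin (shNT), a hairpin against LATS1 (shLATS1B) or hairpins labelled as targeting LATS1 and LATS2 (shLATS1+2). Infected cells were selected in puromycin at 1.5 µg/ml for 4 days and left to recover for 7 days or longer. Plasmid cDNA was then delivered by transient lipid transfection, and RNA was taken after 5 days in an estrogen-containing medium. Each array received labelled cDNA made from 100 ng of total RNA.

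The deposited table holds 1 column of log2 values per array for 32321 probe sets, with values from 3.561 to 13.75. The submitters' processing notes name the R package affy for these deposited log2 values, with no version, and the background correction, normalization and summary method are not given in the sources used here. Array medians lay between 5.494 and 5.619, so the deposited values had been brought to a common scale by some step between arrays. Within groups, arrays correlated with r between 0.993 and 0.998 across probe sets, and no 2 columns held identical values. Nothing in the labels says that the 3 replicates of a group came from separate cultures, so the p-values measure only the spread between these samples. The number of arrays limits the precision.

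Probe sets were named from the platform annotation, in which 19158 had exactly 1 gene symbol, 1388 had several and 11775 had none. Symbols were updated through a RefSeq gene table of assembly GRCh38.p14, to which 19128 probe sets matched by gene identifier. No genome build is given for the array values. Coordinates entered only through the genomic span of genes, taken from the RefSeq gene table for an added relation. For each of 18404 genes, the probe set with the highest mean over the 18 arrays was kept, which decided between several probe sets for 637 genes. No filter on brightness was applied. Where in a transcript a probe set lies was not analysed here, so a probe set can miss the part of a gene that a transfected cDNA carries.

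All 18 arrays entered 1 linear model with a mean per group, fitted in R 4.3.3 with limma 3.58.1 (its functions lmFit, contrasts.fit and eBayes). The model left 12 residual degrees of freedom, to which the moderation added 3.94. Every test was two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 18404 genes of a comparison. A gene was called changed at an adjusted p under 0.05. The 7 comparisons were each knockdown against the control arrays, the knockdowns against each other, each cDNA treatment against the control arrays, and the interaction of the YAP/TAZ and ESR1 cDNAs. The interaction is the change from ESR1 cDNA to both cDNAs minus the change from control cDNA to YAP/TAZ cDNA, on the log2 scale.

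A set of 16 gene lists, covering pathways, mammary cell types and other cell types, was written before the data were examined, as were the tests, the alternatives and the rule for naming genes. These lists were the YAP/TAZ targets, estrogen response, luminal, basal and myoepithelial, mesenchymal, epidermal differentiation, interferon response, cell cycle, NF-kB and inflammatory cytokine, cholesterol synthesis, hypoxia and glycolysis, p53 target, unfolded protein and amino acid stress, Hippo component, ribosomal protein, and leukocyte and endothelial genes. Each list was tested with limma's camera at its preset correlation of 0.01, adjusted over the 16 lists of a comparison. The same test with an estimated correlation and limma's fry were alternatives. Where the estimated correlation was above the preset, as for interferon and cell cycle genes (0.19 each), the preset gave much smaller p-values. Beside each list's count over all genes stands the count adjusted over the list alone.

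The naming rule took, for each comparison, the 5 targeted or transfected genes and the 10 largest rises and 10 largest falls among called genes whose 3 arrays in 1 group all lay beyond the 3 of the other. For the interaction it took the 5 largest values of each sign. Of each list it took up to 4 called members with the largest absolute change. Standard errors are those of the moderated fit, and fold changes are 2 to the power of the absolute log2 change.

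Knockdown and cDNA profiles were compared by covariance and Pearson's r across genes, which are not independent replicates. These profiles share the 3 control arrays, so unchanged groups were simulated against the same controls in 100 draws. With 3 control arrays, the controls could not be split with at least 2 in each part. Differences that share no array were added after the data had been seen. So was a count of genes whose values in the 9 arrays on 1 side of the first component all lay beyond those of the other 9, and a count of interaction calls in 100 draws with the residuals of the 18 arrays exchanged.

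The fit was tested on simulated data for the comparison of shLATS1+2 with the control arrays, with 200 of 18404 genes changed. At 1.5-fold it recovered 96% of them with 11 false calls. At 2-fold it recovered 100% with 10 false calls, and at 3-fold also 100% with 10. The simulated noise was independent between genes, whereas a common axis held 46.7% of the real variance within groups. These rates therefore need not carry over to the real arrays.

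Alternatives written in advance were the replicate number as a block, quantile normalization, centring on array medians, a filter on dim genes, another rule for probe sets, all probe sets, trended and robust moderation, array weights, fits of the compared groups alone, a 1.5-fold threshold and leaving out each array. A fit without 2 arrays that stood apart from their groups and a fit with a within-group component as a covariate were added after the data had been seen. So were 2 further gene lists, of glucocorticoid receptor targets and of NRF2 targets.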

Results

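The 18 arrays covered 6 groups of MCF10A cells with 3 arrays each. In 4 groups the cells carried a non-targeting hairpin and received a control cDNA, a YAP/TAZ cDNA, an ESR1 cDNA, or YAP/TAZ plus ESR1 cDNA. The other 2 groups received the control cDNA and carried a hairpin against LATS1 (shLATS1B) or hairpins labelled as targeting LATS1 and LATS2 (shLATS1+2). LATS1 and LATS2 are the Hippo pathway kinases that phosphorylate and restrain the transcriptional co-activators YAP (gene YAP1) and TAZ (gene WWTR1), and ESR1 encodes estrogen receptor alpha. The arrays with the non-targeting hairpin and control cDNA are called the control arrays.

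The targeted genes were read in every array first. LATS1 (probe set 8130116) had a mean log2 intensity of 8.86 ± 0.086 (SD, n = 3) in the control arrays, 7.66 ± 0.13 in the shLATS1B arrays and 7.76 ± 0.090 in the arrays labelled shLATS1+2. The 6 knockdown arrays lay between 7.57 and 7.85. All were below the lowest of the other 12 arrays, at 8.64. LATS2 (probe set 7970498) was not lower in the arrays labelled shLATS1+2, at 7.82 ± 0.090 against 7.73 ± 0.10 in the control arrays. The values therefore do not bear out the LATS2 part of that label. YAP1 (probe set 7943398) stood at 10.79 ± 0.029 in the arrays labelled YAP/TAZ cDNA and 10.84 ± 0.031 in the control arrays, and WWTR1 (probe set 8091422) at 9.44 ± 0.047 and 9.57 ± 0.16. A transfected YAP or TAZ cDNA is therefore not visible in the YAP/TAZ arrays at these probe sets. This checks the label only if the probe sets read the transfected sequence. ESR1 (probe set 8122843) rose from 5.53 ± 0.14 to 6.47 ± 0.10 with ESR1 cDNA and to 6.03 ± 0.079 with both cDNAs. It also stood at 6.37 ± 0.11 in the shLATS1B arrays and 6.40 ± 0.055 in the arrays labelled shLATS1+2. Both of these groups received control cDNA, so a raised ESR1 value does not mark the arrays labelled with ESR1 cDNA. Against the median gene, at 6.40, the ESR1 signal was dim in the control arrays. No background level was estimated, and 5.208, the percentile 30 of gene means, served as the cutoff for dim genes. A group mean under this cutoff was treated as near background, and a fold against it as a lower bound. Among the genes given here this applied to CYP24A1, OLR1, PNLIPRP3 and DCN with either knockdown and IL6 with shLATS1+2. It also applied to DCN with either single cDNA, ANKRD1 with ESR1, and SLC6A14, CYP24A1 and INSC with both cDNAs.

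**Figure D1:**
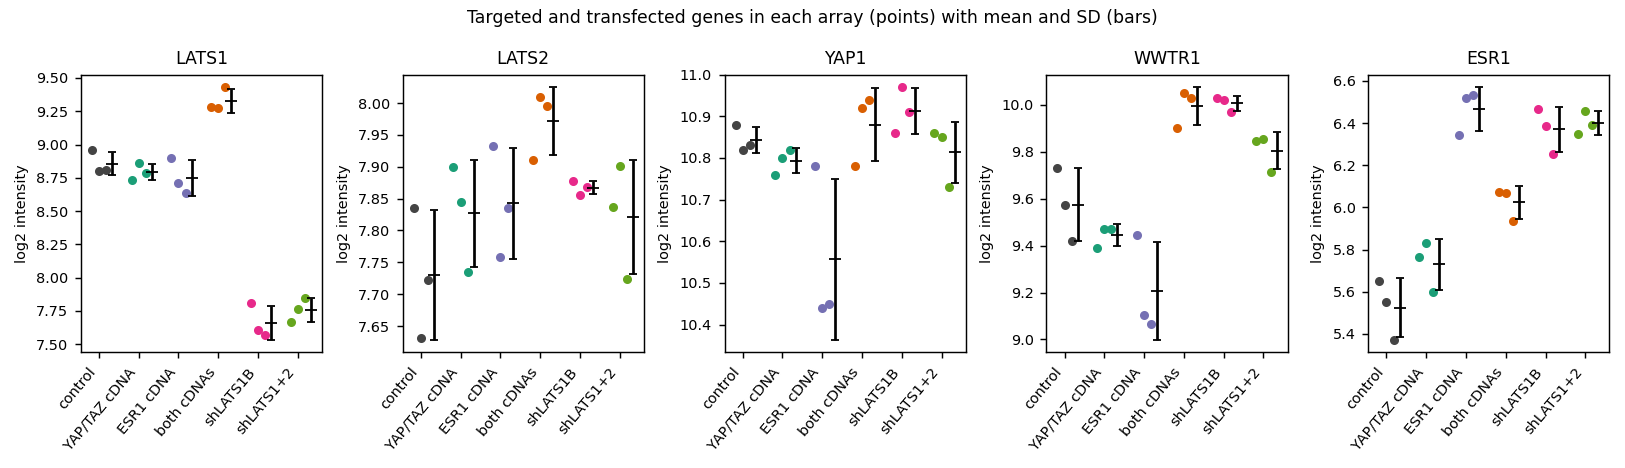
Log2 intensity of LATS1, LATS2, YAP1, WWTR1 and ESR1 in each of the 18 arrays (points) by group, with the mean and SD of each group of 3 (bars); each panel has its own axis. LATS1 is lowest in both knockdown groups (7.66 and 7.76), LATS2 is not lower in the shLATS1+2 group (7.82), and ESR1 is above the control mean of 5.53 in all 5 other groups.

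A principal component analysis of the 18404 genes set 9 arrays against the other 9. The first component held 47.3% of the variance and parted the control, YAP/TAZ and ESR1 arrays (scores from -23.0 to -10.3) from the arrays with both cDNAs and both knockdowns (scores from 9.83 to 22.7). No group had arrays on both sides. The labels name no batch or day, so for changes that follow this division a batch and the group cannot be told apart. Changes that also part arrays on 1 side do not follow it alone. LATS1 lay between 7.57 and 7.85 in the knockdown arrays and between 9.27 and 9.43 with both cDNAs, and interferon genes were higher with either single cDNA (means 8.86 and 9.31) than in the control arrays (7.17). Comparisons within 1 side are those of the single cDNAs with the control arrays and of the knockdowns with each other.

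**Figure D2:**
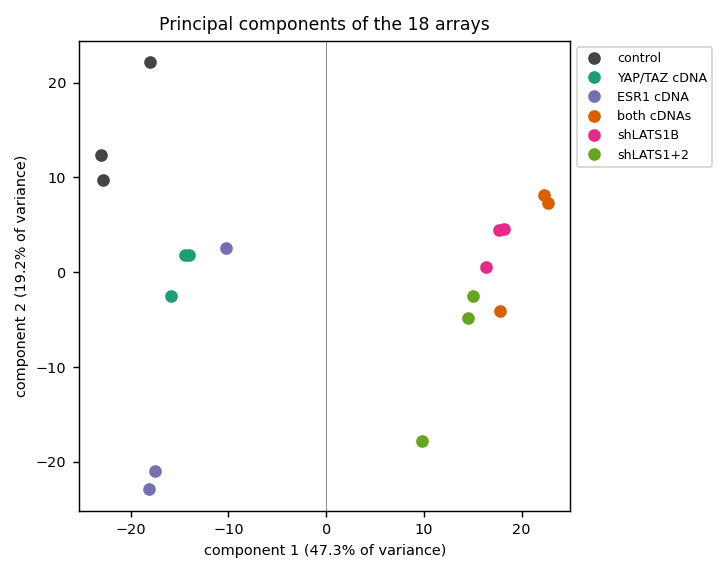
Scores of the 18 arrays on the first 2 principal components of the 18404 genes, coloured by group; the components hold 47.3% and 19.2% of the variance. The 9 arrays left of 0 are the control, YAP/TAZ and ESR1 arrays, and the 9 right of 0 are those with both cDNAs or a LATS knockdown.

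The question of the shLATS1B arrays was which transcripts change with LATS1 knockdown under control cDNA. LATS1 fell 2.29-fold against the control arrays (log2 change -1.19 ± 0.078 SE, 3 against 3 arrays; limma, adjusted p = 6.1e-09). Interferon-induced genes were among the steepest rises: IFIT1, which binds viral RNA, at 22.5-fold (log2 4.49 ± 0.19), the RNA-sensing synthetase OAS2 at 12.7-fold (3.66 ± 0.12), the antiviral enzyme RSAD2 at 10.8-fold (3.43 ± 0.093) and the chemokine CXCL10 at 10.5-fold (3.39 ± 0.20). CYP24A1, the enzyme that inactivates vitamin D, rose 18.1-fold (4.17 ± 0.10), the water and glycerol channel AQP3 rose 11.4-fold (3.52 ± 0.074) and the scavenger receptor OLR1 rose 9.66-fold (3.27 ± 0.14). The largest falls included the lipase-related gene PNLIPRP3 (11-fold, log2 -3.46 ± 0.15), SCNN1G, a subunit of the epithelial sodium channel (10.7-fold, -3.42 ± 0.096), the spindle orientation adaptor INSC (8.19-fold, -3.03 ± 0.12), the protease inhibitor SERPINA3 (6.42-fold, -2.68 ± 0.13) and the basal keratin KRT14 (5.96-fold, -2.57 ± 0.14). Among the other targeted genes, ESR1 rose 1.80-fold (0.85 ± 0.081) and WWTR1 1.35-fold (0.43 ± 0.089). LATS2 (0.14 ± 0.063, adjusted p = 0.14) and YAP1 (0.0684 ± 0.075, adjusted p = 0.61) did not pass.

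Of 29 measured interferon genes, 27 rose and 0 fell in the shLATS1B arrays, with 27 and 0 adjusted over the list alone (median log2 change 1.90; limma's camera, adjusted p = 5.1e-40, and 0.00081 with an estimated correlation). Cholesterol synthesis genes rose, 13 of 15, with 13 adjusted over the list alone (median 0.38, adjusted p = 2.8e-08). They included INSIG1, which retains the sterol sensor in the endoplasmic reticulum (3.35-fold, 1.75 ± 0.047), and the synthase HMGCS1 (1.97-fold, 0.98 ± 0.067). Of 30 cell cycle genes 0 rose and 19 fell, with 1 and 19 adjusted over the list alone (median -0.32, adjusted p = 3.5e-09; adjusted p = 0.054 with an estimated correlation). The kinetochore motor CENPE fell 2.28-fold (-1.19 ± 0.13) and the checkpoint kinase BUB1B 1.73-fold (-0.79 ± 0.12). Of NF-kB and cytokine genes 13 of 23 rose and 4 fell, and 15 and 5 adjusted over the list alone (median 0.31, adjusted p = 0.00027; adjusted p = 0.094 with an estimated correlation). TNFAIP2 rose 7.98-fold (3.00 ± 0.11) and the iron-binding protein LCN2 3.52-fold (1.82 ± 0.084). The chemokine CCL20 fell 2.79-fold (-1.48 ± 0.19).

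Markers of epithelial state moved in both directions. Luminal genes rose, 10 of 24 with 3 lower and 11 and 3 adjusted over the list alone (median 0.0896, adjusted p = 0.0062). They were led by the transcription factor ELF3 (4.85-fold, 2.28 ± 0.11) and the keratin KRT8 (2.14-fold, 1.10 ± 0.13), and the surface antigen CD24 fell 1.64-fold (-0.71 ± 0.060). Basal and myoepithelial genes fell, 8 of 18 with 3 higher and the same counts adjusted over the list alone (median -0.0249, adjusted p = 0.026; adjusted p = 0.34 with an estimated correlation). KRT14, the actin-binding protein TAGLN (4.07-fold, -2.02 ± 0.12) and the peptidase MME (3.44-fold, -1.78 ± 0.12) fell. The call for this list was lost without control array 1 (median 0.0073, adjusted p = 0.12). Epidermal differentiation genes fell, 7 of 29 with 1 higher and the same counts adjusted over the list alone (median -0.087, adjusted p = 0.0067). They included the cornified envelope genes SPRR1B (2.98-fold, -1.57 ± 0.12) and TGM1 (2.29-fold, -1.19 ± 0.098). Estrogen response genes rose, 12 of 26 with 1 lower and 12 and 3 adjusted over the list alone (median 0.0748, adjusted p = 0.0057; adjusted p = 0.25 with an estimated correlation). IGFBP4 (2.77-fold, 1.47 ± 0.13), which binds insulin-like growth factors, the small GTPase RERG (2.49-fold, 1.32 ± 0.077) and the receptor co-repressor NRIP1 (1.83-fold, 0.87 ± 0.044) were among them. p53 targets rose, 7 of 18 with 1 lower and the same counts adjusted over the list alone (median 0.0738, adjusted p = 0.0063; adjusted p = 0.13 with an estimated correlation). The stress cytokine GDF15 rose 4.11-fold (2.04 ± 0.041).

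YAP/TAZ targets did not pass as a list with camera in the shLATS1B arrays: 9 of 22 rose and 3 fell, with 10 and 3 adjusted over the list alone (median 0.14, camera adjusted p = 0.067). The list did pass, as higher, with the alternative test fry (adjusted p = 0.0094). CCN1, a matricellular growth regulator, rose 1.85-fold (0.89 ± 0.088) and AMOTL2, a YAP-binding scaffold, 1.58-fold (0.66 ± 0.063), while the surface nucleotidase NT5E fell 2.18-fold (-1.12 ± 0.050). Lists of mesenchymal (2 higher, 7 lower of 24), unfolded protein (4 and 6 of 20), ribosomal (1 and 3 of 26), hypoxia (7 and 7 of 19) and Hippo genes (4 and 4 of 24) had camera adjusted p-values of 0.13, 0.31, 0.43, 0.84 and 0.84. Counts adjusted over the list alone had 1 more lower member in each of these but the ribosomal list. Within them the matrix protein FN1 fell 3.38-fold (-1.76 ± 0.091) and the repressor SNAI2 2.67-fold (-1.41 ± 0.057). Of 23 leukocyte and endothelial markers 3 rose, CD14 by 3.54-fold (1.82 ± 0.098), CD68 by 1.87-fold and PECAM1 by 1.47-fold, and the list did not pass (3 and 0 adjusted over the list alone, adjusted p = 0.34). For that list the median (-0.00393) and mean (0.13) differed in sign, as they did for Hippo genes (0.0149 and -0.0227). With fry, the mesenchymal (adjusted p = 7e-06), unfolded protein (8.6e-05) and leukocyte and endothelial (9.8e-05) lists passed. In all, 4415 of 18404 genes changed, 2286 higher and 2129 lower. The higher share was 51.8%, and 47.4% of 4016 with arrays centred on their medians. Quantile normalization gave 48.9%, and of 926 genes changed at least 1.5-fold 566 were higher. This comparison crosses the division of the arrays on the first component.

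In the arrays labelled shLATS1+2, compared with the control arrays to ask what follows when both kinases are targeted, LATS1 fell 2.14-fold (log2 -1.10 ± 0.078, 3 against 3 arrays; limma, adjusted p = 1.8e-08). LATS2 did not fall (0.0905 ± 0.063, adjusted p = 0.37), so these arrays are described by their label. The steepest rises were again of interferon-induced genes: IFIT1 at 30.6-fold (4.94 ± 0.19), CXCL10 at 14.7-fold (3.88 ± 0.20), OAS2 at 13.5-fold (3.75 ± 0.12) and RSAD2 at 13.3-fold (3.73 ± 0.093). OLR1 (11.6-fold, 3.54 ± 0.14), CYP24A1 (10.8-fold, 3.43 ± 0.10) and TNFSF10, which encodes the death ligand TRAIL (10.5-fold, 3.39 ± 0.21), followed. SCNN1G (9.58-fold, -3.26 ± 0.096), INSC (8.31-fold, -3.05 ± 0.12), PNLIPRP3 (8.22-fold, -3.04 ± 0.15), SERPINA3 (5.86-fold, -2.55 ± 0.13) and ANGPTL4, an inhibitor of lipoprotein lipase (5.27-fold, -2.40 ± 0.050), had the largest falls. ESR1 rose 1.84-fold (0.88 ± 0.081), and neither WWTR1 (0.23 ± 0.089, adjusted p = 0.072) nor YAP1 (-0.0335 ± 0.075, adjusted p = 0.83) passed.

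Interferon genes rose, 27 of 29, with 27 adjusted over the list alone (median 1.99; limma's camera, adjusted p = 2.5e-42, and 0.00062 with an estimated correlation). Cholesterol synthesis genes rose, 11 of 15, with 11 adjusted over the list alone (median 0.41, adjusted p = 2.6e-08). INSIG1 rose 2.93-fold (1.55 ± 0.047) and HMGCS1 1.87-fold (0.91 ± 0.067). Cell cycle genes fell, 19 of 30 with 1 higher and 23 and 1 adjusted over the list alone (median -0.33, adjusted p = 2.6e-09). Among them were CENPE (2.25-fold, -1.17 ± 0.13), BUB1B (1.99-fold, -0.99 ± 0.12) and the proliferation antigen MKI67 (1.52-fold, -0.60 ± 0.12). NF-kB and cytokine genes rose, 13 of 23 with 4 lower and 14 and 5 adjusted over the list alone (median 0.34, adjusted p = 9.2e-06). They included TNFAIP2 at 7.77-fold (2.96 ± 0.11), LCN2 at 3.96-fold (1.99 ± 0.084) and the cytokine IL6 at 2.72-fold (1.44 ± 0.12). Luminal genes rose, 10 of 24 with 3 lower and 11 and 3 adjusted over the list alone (median 0.12, adjusted p = 0.0017). They included ELF3 at 5.57-fold (2.48 ± 0.11) and the adhesion molecule EPCAM at 1.64-fold (0.72 ± 0.039). Basal and myoepithelial genes fell, 8 of 18 with 1 higher and 8 and 2 adjusted over the list alone (median -0.13, adjusted p = 0.0011; adjusted p = 0.21 with an estimated correlation). KRT14 (5.15-fold, -2.36 ± 0.14) and TAGLN (4.51-fold, -2.17 ± 0.12) were in front. Epidermal differentiation genes fell, 10 of 29 with 1 higher and the same counts adjusted over the list alone (median -0.0878, adjusted p = 0.009), SPRR1B by 3.27-fold (-1.71 ± 0.12).

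Mesenchymal genes fell in the arrays labelled shLATS1+2, 9 of 24 with 2 higher and the same counts adjusted over the list alone (median -0.0107, adjusted p = 0.039; adjusted p = 0.060 with an estimated correlation). DCN, a matrix proteoglycan (4.35-fold, -2.12 ± 0.19), FN1 (3.59-fold, -1.84 ± 0.091) and the intermediate filament VIM (2.18-fold, -1.12 ± 0.087) fell. The list's call was lost without control array 3 (adjusted p = 0.054) or shLATS1+2 array 3 (adjusted p = 0.070, median 0.00223), and among brighter genes (0.14). p53 targets rose, 7 of 18 with 1 lower and 7 and 2 adjusted over the list alone (median 0.0701, adjusted p = 0.032; adjusted p = 0.21 with an estimated correlation), GDF15 by 3.99-fold (2.00 ± 0.041). The p53 call was lost among brighter genes (adjusted p = 0.082). Both calls were lost without ESR1 array 1 and shLATS1+2 array 3, a fit chosen after the data had been seen (0.088 and 0.067). YAP/TAZ targets did not pass as a list (7 higher and 4 lower of 22, with 8 and 5 adjusted over the list alone, median 0.0178, adjusted p = 0.25). CCN1 rose 1.86-fold (0.90 ± 0.088) and NT5E fell 2.20-fold (-1.14 ± 0.050). Estrogen response (7 and 3 of 26), Hippo (1 and 5 of 24), unfolded protein (4 and 6 of 20), ribosomal (3 and 1 of 26), leukocyte and endothelial (3 and 0 of 23) and hypoxia genes (5 and 6 of 19) had adjusted p-values of 0.21, 0.25, 0.30, 0.35, 0.35 and 0.52. Adjusted over the list alone, 6 estrogen response and 7 unfolded protein genes were lower, and the other counts were the same. RERG rose 2.17-fold (1.11 ± 0.077), NDRG1, a stress-responsive gene, fell 4.02-fold (-2.01 ± 0.096), and CD14 rose 3.24-fold (1.70 ± 0.098). The leukocyte median (-0.0229) and mean (0.12) differed in sign. With fry, the estrogen response (adjusted p = 0.0091), hypoxia (0.019), unfolded protein (0.00064) and leukocyte (3e-04) lists passed. The YAP/TAZ targets did not pass with fry either (adjusted p = 0.057). In all, 4564 genes changed, 2174 higher and 2390 lower, again across the division of the arrays on the first component. The majority direction was not stable: the higher share was 47.6%, 37.7% of 4438 with arrays centred on their medians and 51.8% of 5426 with all probe sets. Of 940 genes changed at least 1.5-fold, 527 were higher and 413 lower.

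Both knockdown profiles moved many genes in the same direction. Of genes called in both, 3357 changed in the same direction (1699 higher, 1658 lower) and 6 in opposite directions. Independent lists of these lengths would share 270 higher and 276.5 lower genes. Across genes the correlation was 0.918, where unchanged groups simulated against the same control arrays gave 0.50. That value follows from the shared controls by construction and holds only where no gene changes. Part of the likeness of the knockdowns can come from the shared control arrays, and both profiles cross the division on the first component.

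Set directly against each other, the arrays labelled shLATS1+2 and the shLATS1B arrays differed in 59 genes, 26 higher and 33 lower (limma, adjusted p under 0.05, 3 against 3 arrays). The majority direction was not stable: of 20 genes changed at least 1.5-fold 14 were higher and 6 lower, and the higher share was 44.1% in all, 54% with only these groups in the fit and 56.8% without shLATS1+2 array 3. PXDN, a peroxidase of the extracellular matrix, was 2.87-fold lower (log2 -1.52 ± 0.076, adjusted p = 1.8e-08) in the arrays labelled shLATS1+2. SLFN13, a ribonuclease of the Schlafen family, was 2.31-fold lower (-1.21 ± 0.091) and the amino acid transporter SLC6A14 was 1.93-fold lower (-0.95 ± 0.11). Higher there were the ERBB4 ligand NRG4 (1.99-fold, 1.00 ± 0.096), the glutathione peroxidase GPX2 (1.91-fold, 0.94 ± 0.13), the lipopolysaccharide receptor TLR4 (1.80-fold, 0.85 ± 0.13), the proprotein convertase PCSK5 (1.76-fold, 0.82 ± 0.079) and the NF-kB regulator TNIP3 (1.72-fold, 0.78 ± 0.076). The cystine transporter SLC7A11, which had fallen in both knockdowns, was 1.33-fold higher (0.41 ± 0.041). None of the 5 targeted genes differed, with LATS1 at 0.0989 ± 0.078 (adjusted p = 0.60), LATS2 at -0.0467 ± 0.063 (adjusted p = 0.79), YAP1 at -0.10 ± 0.075 (adjusted p = 0.57), WWTR1 at -0.20 ± 0.089 (adjusted p = 0.41) and ESR1 at 0.0309 ± 0.081 (adjusted p = 0.91). No direction here can be tied to LATS2.

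As lists, 5 differed between the arrays labelled shLATS1+2 and the shLATS1B arrays with camera's preset correlation and 0 with an estimated one. Interferon genes were higher (median 0.11, adjusted p = 7.3e-06; adjusted p = 0.39 with an estimated correlation), with 0 of 29 called over all genes and 5 adjusted over the list alone. Estrogen response genes were lower (median -0.11, adjusted p = 0.00036; adjusted p = 0.39 with an estimated correlation), with 0 of 26 called over all genes and 1 adjusted over the list alone. Ribosomal genes were higher (median 0.0645, adjusted p = 0.00096; adjusted p = 0.43 with an estimated correlation), with 0 of 26 called and 0 adjusted over the list alone. Basal and myoepithelial genes were lower (median -0.12, adjusted p = 0.027; adjusted p = 0.43 with an estimated correlation), with 0 of 18 called and 0 adjusted over the list alone. NF-kB and cytokine genes were higher (median 0.0566, adjusted p = 0.029; adjusted p = 0.43 with an estimated correlation), with 0 higher and 1 lower of 23 over all genes, and 4 and 1 adjusted over the list alone. Without shLATS1+2 array 3, the ribosomal (adjusted p = 0.14), cytokine (0.26) and basal (0.065) calls were lost. The cytokine call was also lost without shLATS1B array 3 (0.15), and the basal call without array 2 of either group (0.053 and 0.056). Among brighter genes the basal (0.15) and cytokine (0.058) calls were lost, and with fry all 5 were (adjusted p from 0.096 to 0.25). The ribosomal (0.11) and cytokine (0.24) calls were also lost without ESR1 array 1 and shLATS1+2 array 3, a fit chosen after the data had been seen. The remaining 11 lists did not pass (adjusted p from 0.067 to 0.88; at most 1 member called over all genes and 3 adjusted over the list alone), and of these the unfolded protein, epidermal and cell cycle lists had a test, mean or median of different sign. The gene count fell to 33 without shLATS1B array 2, 35 without shLATS1B array 3 and 37 without shLATS1+2 array 3, and rose to 248 with array weights. It rose much further with a within-group component as a covariate, a fit chosen after the data had been seen.

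The arrays labelled YAP/TAZ cDNA were compared with the control arrays for the effect of these co-activators in cells with the non-targeting hairpin. Neither YAP1 (-0.0514 ± 0.075, limma adjusted p = 0.83) nor WWTR1 (-0.13 ± 0.089, adjusted p = 0.53) was higher, so directions here follow the label alone. IFIT1 rose 16.1-fold (log2 4.00 ± 0.19, 3 against 3 arrays), OAS2 13.2-fold (3.72 ± 0.12), RSAD2 7.04-fold (2.81 ± 0.093), the interferon-induced membrane protein IFITM1 6.29-fold (2.65 ± 0.045) and complement factor CFB 5.91-fold (2.56 ± 0.094). The largest falls were smaller: DCN (2.90-fold, -1.54 ± 0.19), INSC (2.54-fold, -1.35 ± 0.12), the growth factor carrier FGFBP1 (2.37-fold, -1.24 ± 0.071), the tetraspanin TSPAN7 (2.01-fold, -1.0 ± 0.10) and the signalling ligand WNT7A (1.97-fold, -0.98 ± 0.11). LATS1 (-0.062 ± 0.078, adjusted p = 0.80), LATS2 (0.0966 ± 0.063, adjusted p = 0.51) and ESR1 (0.21 ± 0.081, adjusted p = 0.17) did not pass.

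YAP/TAZ targets rose in the arrays labelled YAP/TAZ cDNA, 8 of 22 with 1 lower, and 10 and 1 adjusted over the list alone (median 0.18; limma's camera, adjusted p = 2.2e-07). The rise was not particular to this label: between the ESR1 and YAP/TAZ arrays the list did not pass (median 0.00224, camera adjusted p = 0.24). CCN1 rose 2.12-fold (1.08 ± 0.088), the secreted protein CCDC80 1.74-fold (0.80 ± 0.082), AMOTL2 1.57-fold (0.65 ± 0.063) and the matricellular factor CCN2 1.51-fold (0.60 ± 0.071). Interferon genes rose, 27 of 29, with 27 adjusted over the list alone (median 1.63, adjusted p = 1.3e-78, and 2.7e-05 with an estimated correlation). NF-kB and cytokine genes rose, 16 of 23, with 16 adjusted over the list alone (median 0.36, adjusted p = 8.3e-22). They included CCL20 (2.75-fold, 1.46 ± 0.19), LCN2 (2.33-fold, 1.22 ± 0.084) and the acute phase protein SAA1 (2.20-fold, 1.14 ± 0.089). Cell cycle genes fell, 13 of 30 with 0 higher, and 19 and 1 adjusted over the list alone (median -0.26, adjusted p = 6.1e-14). The ubiquitin-conjugating enzyme UBE2C fell 1.35-fold (-0.43 ± 0.041) and the mitotic kinase AURKB 1.45-fold (-0.53 ± 0.061). Cholesterol synthesis genes fell, 6 of 15, with 8 adjusted over the list alone (median -0.16, adjusted p = 9.3e-08), HMGCS1 by 1.37-fold (-0.46 ± 0.067) and INSIG1 by 1.35-fold (-0.43 ± 0.047). p53 targets rose, 7 of 18, with 9 adjusted over the list alone (median 0.14, adjusted p = 8.1e-08). Unfolded protein and amino acid stress genes rose, 5 of 20, with 6 higher and 1 lower adjusted over the list alone (median 0.0945, adjusted p = 0.00087). The p53-induced gene TP53INP1 rose 1.72-fold (0.79 ± 0.085), and the stress factor DDIT3 2.19-fold (1.13 ± 0.14).

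Luminal genes rose, 4 of 24 with 1 lower and 5 and 2 adjusted over the list alone (median 0.05, adjusted p = 0.0067), led by the epithelial transcription factor EHF (2.83-fold, 1.50 ± 0.074). Epidermal differentiation genes rose, 6 of 29, with 6 adjusted over the list alone (median 0.0591, adjusted p = 0.0083), led by the calcium-binding proteins S100A8 (4.34-fold, 2.12 ± 0.23) and S100A9 (2.70-fold, 1.43 ± 0.12). Hypoxia and glycolysis genes fell, 4 of 19 with 2 higher and the same counts adjusted over the list alone (median -0.0615, adjusted p = 0.020; adjusted p = 0.24 with an estimated correlation), the aldolase ALDOC by 1.73-fold (-0.79 ± 0.11). Ribosomal genes fell, 2 of 26, with 2 adjusted over the list alone (median -0.0346, adjusted p = 0.038; adjusted p = 0.58 with an estimated correlation). The hypoxia call was lost without control array 2 (adjusted p = 0.081), and the ribosomal call without control array 2 (0.12), control array 3 (0.14) or YAP/TAZ array 2 (0.19). The ribosomal call was also lost with quantile normalization (0.075), among brighter genes (0.10) and with fry (0.25), and stood at the threshold (0.05) without ESR1 array 1 and shLATS1+2 array 3. Estrogen response (4 and 0 of 26), mesenchymal (1 and 4 of 24), basal and myoepithelial (1 and 3 of 18), Hippo (0 and 1 of 24) and leukocyte and endothelial genes (1 and 1 of 23) did not pass (adjusted p = 0.093, 0.19, 0.72, 0.89 and 0.90). Adjusted over the list alone, these counts were 4 and 1, 1 and 5, 3 and 3, 1 and 2, and 1 and 1. FN1 rose 3.00-fold (1.59 ± 0.091), RERG rose 2.03-fold (1.02 ± 0.077) and KRT14 fell 1.65-fold (-0.73 ± 0.14). The basal median (0.0381) and mean (-0.0172) differed in sign, as did the leukocyte median (-0.00225) and mean (0.0102). In all, 1289 genes changed, 582 higher and 707 lower, and 848 did without YAP/TAZ array 2. The count was 1945 without ESR1 array 1 and shLATS1+2 array 3, and 2825 with a within-group component as a covariate, both chosen after the data had been seen. Of 191 genes changed at least 1.5-fold, 146 were higher and 45 lower.

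ESR1 cDNA was compared with control cDNA for the effect of the receptor in cells with the non-targeting hairpin. ESR1 itself rose 1.92-fold (log2 0.94 ± 0.081, 3 against 3 arrays; limma, adjusted p = 5.1e-07). Since ESR1 was nearly as high in both knockdown groups, which received control cDNA, this rise does not by itself bear out the label. Interferon-induced genes rose most, IFIT1 by 32.9-fold (5.04 ± 0.19), OAS2 by 18.7-fold (4.23 ± 0.12), RSAD2 by 11.1-fold (3.47 ± 0.093) and the chemokine CXCL11 by 9.49-fold (3.25 ± 0.21). CLTRN, which encodes the membrane protein collectrin, rose 7.07-fold (2.82 ± 0.22). INSC (3.78-fold, -1.92 ± 0.12), DCN (3.04-fold, -1.60 ± 0.19), the iron-regulated aconitase ACO1 (2.78-fold, -1.48 ± 0.093), SERPINA3 (2.78-fold, -1.48 ± 0.13) and the glycoprotein hormone STC1 (2.52-fold, -1.33 ± 0.086) had the largest falls. WWTR1 fell 1.29-fold (-0.37 ± 0.089, adjusted p = 0.0078) and YAP1 1.22-fold (-0.28 ± 0.075, adjusted p = 0.014), calls lost when the 6 compared arrays were fitted alone (adjusted p = 0.14 and 0.15). The YAP1 call was also lost without ESR1 array 2 (adjusted p = 0.082) or 3 (0.079). LATS1 (-0.11 ± 0.078, adjusted p = 0.39) and LATS2 (0.11 ± 0.063, adjusted p = 0.25) did not pass.

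Estrogen response genes did not pass as a list with ESR1 cDNA: 4 of 26 rose and 4 fell, with 4 and 4 adjusted over the list alone (median 0.0217; limma's camera, adjusted p = 0.43). RERG rose 2.39-fold (1.26 ± 0.077) and the keratin KRT13 1.52-fold (0.61 ± 0.076). YAP/TAZ targets rose, 10 of 22 with 2 lower and the same counts adjusted over the list alone (median 0.16, adjusted p = 3e-05). CCDC80 rose by 2.32-fold (1.21 ± 0.082), CCN1 by 2.23-fold (1.16 ± 0.088), AMOTL2 by 2.01-fold (1.01 ± 0.063) and the muscle ankyrin repeat gene ANKRD1 by 1.73-fold (0.79 ± 0.072). Interferon genes rose, 27 of 29, with 27 adjusted over the list alone (median 1.96, adjusted p = 6.8e-58, and 0.00013 with an estimated correlation). NF-kB and cytokine genes rose, 17 of 23, with 17 adjusted over the list alone (median 0.47, adjusted p = 4.6e-16), led by the cytokine IL24 (3.82-fold, 1.93 ± 0.090). Cell cycle genes fell, 23 of 30 with 1 higher and 25 and 1 adjusted over the list alone (median -0.40, adjusted p = 1.2e-14), BUB1B by 2.10-fold (-1.07 ± 0.12). p53 targets rose, 10 of 18 with 1 lower and 11 and 2 adjusted over the list alone (median 0.20, adjusted p = 1e-05). Hypoxia and glycolysis genes fell, 10 of 19 with 2 higher and the same counts adjusted over the list alone (median -0.19, adjusted p = 3.1e-05), NDRG1 by 2.35-fold (-1.24 ± 0.096). Cholesterol synthesis genes fell, 6 of 15, with 8 adjusted over the list alone (median -0.20, adjusted p = 0.0014), HMGCS1 by 1.41-fold (-0.49 ± 0.067).

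Luminal genes rose with ESR1 cDNA, 6 of 24, with 7 higher and 2 lower adjusted over the list alone (median 0.0553, adjusted p = 0.0075), EHF by 3.54-fold (1.82 ± 0.074) and CD24 by 1.93-fold (0.95 ± 0.060). Unfolded protein and amino acid stress genes rose, 7 of 20 with 1 lower and 8 and 2 adjusted over the list alone (median 0.0845, adjusted p = 0.043; adjusted p = 0.054 with an estimated correlation), DDIT3 by 3.04-fold (1.60 ± 0.14) and the glutathione-degrading enzyme CHAC1 by 2.56-fold (1.35 ± 0.12). Hippo (1 and 6 of 24), epidermal (5 and 0 of 29), ribosomal (1 and 3 of 26), basal and myoepithelial (2 and 5 of 18), leukocyte and endothelial (2 and 0 of 23) and mesenchymal genes (2 and 5 of 24) did not pass (adjusted p = 0.15, 0.21, 0.43, 0.43, 0.50 and 0.63). Adjusted over the list alone, 2 Hippo genes rose, and the other counts were the same. The mesenchymal median (0.0294) and mean (-0.0723) differed in sign. With fry, the epidermal list passed (adjusted p = 0.0026). FN1 was 2.38-fold higher (1.25 ± 0.091) and VIM 1.69-fold lower (-0.76 ± 0.087). In all, 3487 genes changed, 1295 higher and 2192 lower. The higher share was 37.1%, and 21.8% of 3748 with arrays centred on their medians, while of 446 genes changed at least 1.5-fold 257 were higher and 189 lower. ESR1 array 1 stood apart from arrays 2 and 3: without it 5461 genes changed and the unfolded protein call was lost (adjusted p = 0.12), as it was among brighter genes (0.054), while 2299 genes changed without array 2. A fit of the 6 compared arrays alone called 1126. Set against each other after the data had been seen, the ESR1 and YAP/TAZ arrays differed in 111 genes, 58 higher and 53 lower with ESR1. Between them YAP/TAZ targets (camera adjusted p = 0.24) and cholesterol genes (0.32) did not pass. Interferon, cell cycle, hypoxia, NF-kB and Hippo genes did (camera adjusted p at most 0.04). With an estimated correlation only the interferon call held (adjusted p = 0.0032). Cell cycle, hypoxia, NF-kB and Hippo genes then had adjusted p = 0.19, 0.077, 0.31 and 0.54. Changes against the control arrays that both groups share are therefore not tied to 1 of these cDNAs.

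The arrays with both cDNAs differed from the control arrays in more genes than any other group against them, 5414, with 2700 higher and 2714 lower (limma, 3 against 3 arrays). Of 1335 changed at least 1.5-fold, 761 were higher and 574 lower. IFIT1 rose 46.6-fold (log2 5.54 ± 0.19), RSAD2 29.9-fold (4.90 ± 0.093), OAS2 24.8-fold (4.63 ± 0.12), SLC6A14 at least 22.5-fold (4.49 ± 0.11), CYP24A1 at least 18.0-fold (4.17 ± 0.10) and LCN2 14-fold (3.81 ± 0.084). SCNN1G fell 10.8-fold (-3.43 ± 0.096), INSC at least 8.51-fold (-3.09 ± 0.12), ANGPTL4 7.32-fold (-2.87 ± 0.050), SERPINA3 6.21-fold (-2.64 ± 0.13) and the sulfate transporter SLC26A2 4.72-fold (-2.24 ± 0.071). ESR1 rose 1.41-fold (0.50 ± 0.081, adjusted p = 0.00013), WWTR1 1.34-fold (0.42 ± 0.089, adjusted p = 0.0015), LATS1 1.39-fold (0.47 ± 0.078, adjusted p = 0.00017) and LATS2 1.18-fold (0.24 ± 0.063, adjusted p = 0.0073). YAP1 did not pass (0.0375 ± 0.075, adjusted p = 0.79). WWTR1 rose about as much in the shLATS1B arrays, which received control cDNA. At these probe sets the values therefore do not bear out the YAP/TAZ part of the label of these arrays either.

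Interferon genes rose with both cDNAs, 27 of 29, with 27 adjusted over the list alone (median 2.50; limma's camera, adjusted p = 7.4e-41, and 0.00073 with an estimated correlation). Cell cycle genes fell, 26 of 30 with 0 higher, and 27 and 1 adjusted over the list alone (median -0.76, adjusted p = 7.4e-20). CENPE fell by 2.68-fold (-1.42 ± 0.13), AURKB by 2.16-fold (-1.11 ± 0.061) and the cyclin CCNB1 by 2.11-fold (-1.07 ± 0.067). p53 targets rose, 12 of 18 with 1 lower and the same counts adjusted over the list alone (median 0.34, adjusted p = 8.4e-08). They included GDF15 at 6.37-fold (2.67 ± 0.041) and the cell cycle inhibitor CDKN1A at 2.02-fold (1.02 ± 0.060). NF-kB and cytokine genes rose, 17 of 23 with 1 lower and the same counts adjusted over the list alone (median 0.42, adjusted p = 6.6e-10), while CCL20 fell 2.94-fold (-1.55 ± 0.19). Cholesterol synthesis genes rose, 11 of 15, with 12 adjusted over the list alone (median 0.36, adjusted p = 5e-07), INSIG1 by 2.66-fold (1.41 ± 0.047). Unfolded protein and amino acid stress genes rose, 9 of 20 with 2 lower and 10 and 2 adjusted over the list alone (median 0.17, adjusted p = 0.00092), DDIT3 by 5.55-fold (2.47 ± 0.14). Luminal genes rose, 11 of 24 with 2 lower and the same counts adjusted over the list alone (median 0.21, adjusted p = 0.00026), ELF3 by 3.98-fold (1.99 ± 0.11). Estrogen response genes rose, 12 of 26 with 3 lower and the same counts adjusted over the list alone (median 0.0821, adjusted p = 0.00036; adjusted p = 0.15 with an estimated correlation). IGFBP4 rose by 3.00-fold (1.58 ± 0.13) and NRIP1 by 2.18-fold (1.12 ± 0.044). Ribosomal genes fell, 9 of 26, with 11 adjusted over the list alone (median -0.12, adjusted p = 0.00036; adjusted p = 0.29 with an estimated correlation).

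YAP/TAZ targets did not pass as a list with camera in the arrays with both cDNAs: 8 of 22 rose and 4 fell, with 9 and 4 adjusted over the list alone (median 0.11, camera adjusted p = 0.052). The list did pass, as higher, with fry (adjusted p = 2.8e-05). The growth factor TGFB2 rose 3.53-fold (1.82 ± 0.093) and CCDC80 2.14-fold (1.10 ± 0.082). Mesenchymal (3 and 8 of 24), basal and myoepithelial (5 and 8 of 18), Hippo (6 and 2 of 24), hypoxia (4 and 8 of 19), leukocyte and endothelial (4 and 0 of 23) and epidermal genes (3 and 7 of 29) had adjusted p-values of 0.056, 0.10, 0.22, 0.22, 0.22 and 0.23. Adjusted over the list alone, 5 epidermal genes rose and 9 fell, and the other counts were the same. KRT14 fell 4.84-fold (-2.27 ± 0.14), TAGLN 4.66-fold (-2.22 ± 0.12) and VIM 2.29-fold (-1.19 ± 0.087). Smooth muscle actin, ACTA2, rose 1.80-fold (0.85 ± 0.12) and CD14 4.03-fold (2.01 ± 0.098). The hypoxia median (0.00899) and mean (-0.0921) differed in sign, as did the leukocyte median (-0.00333) and mean (0.14). With fry, the mesenchymal (adjusted p = 2.7e-06), leukocyte (2.8e-05), basal (0.00041), epidermal (0.0053) and hypoxia (0.0054) lists passed. This comparison crosses the division of the arrays on the first component.

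**Figure D3:**
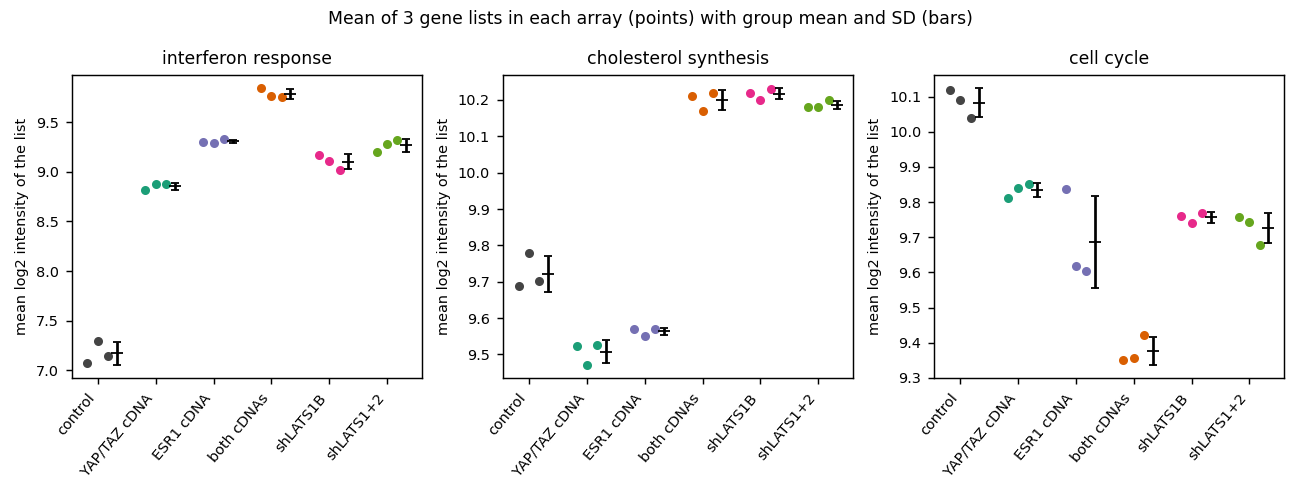
Mean log2 intensity of the interferon, cholesterol synthesis and cell cycle lists in each of the 18 arrays (points) by group, with the mean and SD of each group of 3 (bars). Interferon genes are lowest in the control arrays (mean 7.17, other groups 8.86 to 9.78), and cholesterol synthesis genes stand near 10.2 in the both-cDNA and knockdown arrays against 9.51 to 9.72 in the others.

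The interaction asked whether both cDNAs together departed from the sum of each alone on the log2 scale, and 3512 genes did (2098 above and 1414 below the sum; limma, 12 arrays in 4 groups). SLC6A14 lay 17.6-fold above the sum (log2 4.14 ± 0.15): its means were 5.07 ± 0.083 (SD, n = 3) in the control arrays, 5.21 ± 0.20 with YAP/TAZ, 5.29 ± 0.12 with ESR1 and 9.56 ± 0.11 with both. The first of these lay under the dim cutoff of 5.208 and the next 2 near it, so the exact distance from the sum and its rank are not fixed by these values. The same holds for CYP24A1, at 4.93 with ESR1. CYP24A1 (4.11 ± 0.14), GPX2 (3.71 ± 0.18), the aldo-keto reductase AKR1B10 (3.24 ± 0.21) and the keratin KRT15 (3.20 ± 0.18) were also above. The transcriptional regulator ID2 lay 34.0-fold below the sum (-5.09 ± 0.29): its means were 7.24 ± 0.43, 8.56 ± 0.12, 9.15 ± 0.45 and 5.38 ± 0.22 in the same order. CCL20 (-4.67 ± 0.27), the G-protein regulator RGS2 (-4.64 ± 0.26), SCNN1G (-4.10 ± 0.14) and SLC26A2 (-3.99 ± 0.10) were also below. Of the targeted genes, ESR1 lay below the sum (-0.65 ± 0.11, adjusted p = 0.00076), LATS1 (0.64 ± 0.11, adjusted p = 0.00063) and WWTR1 (0.92 ± 0.13, adjusted p = 7.4e-05) above it, and LATS2 did not pass (0.0324 ± 0.089, adjusted p = 0.87). YAP1 lay above (0.37 ± 0.11, adjusted p = 0.021), a call lost without YAP/TAZ array 1 (adjusted p = 0.051), ESR1 array 2 or 3 (0.063 each), or array 2 (0.055) or 3 (0.059) with both cDNAs.

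Interferon genes, raised by each cDNA alone, lay below the sum with both, 24 of 29, with 25 adjusted over the list alone (median -1.14; limma's camera, adjusted p = 2e-25, and 0.0031 with an estimated correlation). The control mean of this list, 7.17, enters the sum, and its gap of 1.68 to the nearest other group exceeds the distance from the sum. Cholesterol synthesis genes, lowered by each alone and raised by both, lay above the sum, 14 of 15, with 14 adjusted over the list alone (median 0.68, adjusted p = 1.1e-14). Epidermal differentiation genes lay below it, 8 of 29 with 1 above and 9 and 2 adjusted over the list alone (median -0.0614, adjusted p = 0.004), S100A8 by 6-fold (-2.59 ± 0.32). YAP/TAZ targets lay below it, 9 of 22 with 3 above and 10 and 5 adjusted over the list alone (median -0.15, adjusted p = 0.004; adjusted p = 0.17 with an estimated correlation). CCN1 lay 4.51-fold (-2.17 ± 0.12) and CCN2 2.85-fold (-1.51 ± 0.10) below. The NF-kB and cytokine genes lay below it, 7 of 23 with 4 above and 10 and 4 adjusted over the list alone (median -0.21, adjusted p = 0.004; adjusted p = 0.24 with an estimated correlation), SAA1 by 4.77-fold (-2.25 ± 0.13). For YAP/TAZ targets the control mean was 8.02, against 8.25 with YAP/TAZ, 8.30 with ESR1 and 8.25 with both. For NF-kB genes these means were 7.99, 8.47, 8.58 and 8.64. As list means, both departures thus rest largely on the control arrays, whose mean enters the sum. Beneath these means single members moved both ways. From ESR1 cDNA to both cDNAs, 7 YAP/TAZ targets were higher and 8 lower, and of NF-kB genes 9 and 5. The list means therefore do not describe the departure of each member. Hypoxia and glycolysis genes lay above it, 8 of 19 with 1 below and the same counts adjusted over the list alone (median 0.0678, adjusted p = 0.025; adjusted p = 0.40 with an estimated correlation), ALDOC by 5.36-fold (2.42 ± 0.15). Estrogen response genes lay above it, 8 of 26 with 2 below and 11 and 2 adjusted over the list alone (median 0.12, adjusted p = 0.030; adjusted p = 0.54 with an estimated correlation). IGFBP4 lay above by 3.20-fold (1.68 ± 0.19) and RERG below by 2.37-fold (-1.24 ± 0.11). Hippo genes lay above it, 7 of 24 with 3 below and 9 and 3 adjusted over the list alone (median 0.24, adjusted p = 0.042; adjusted p = 0.56 with an estimated correlation). The estrogen call was lost without control array 1 (adjusted p = 0.073) or YAP/TAZ array 1 (0.056), and the Hippo call without control array 1 (0.073), YAP/TAZ array 1 (0.059), ESR1 array 2 (0.096) or 3 (0.070), or array 3 with both cDNAs (0.075). Among brighter genes the estrogen (0.056), hypoxia (0.059) and Hippo (0.090) calls were lost, and the Hippo call also with quantile normalization (0.12) and fry (0.059).

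Basal and myoepithelial (3 above and 6 below of 18), ribosomal (0 and 1 of 26), cell cycle (0 and 4 of 30), p53 (6 and 3 of 18), mesenchymal (4 and 3 of 24), leukocyte and endothelial (4 and 1 of 23), luminal (7 and 6 of 24) and unfolded protein genes (3 and 2 of 20) did not pass the interaction test (adjusted p = 0.054, 0.14, 0.14, 0.27, 0.46, 0.48, 0.82 and 0.87). Adjusted over the list alone, the counts were 4 and 8 for basal, 0 and 0 for ribosomal, 4 and 4 for mesenchymal, 9 and 6 for luminal and 4 and 2 for unfolded protein genes, and the same for the other lists. FN1 lay 13.9-fold below the sum (-3.79 ± 0.13), as it rose with each cDNA and stood at 7.61 ± 0.11 with both against 8.57 ± 0.21 in the control arrays. CD24 lay 3.88-fold below (-1.96 ± 0.085) and GDF15 2.77-fold above (1.47 ± 0.057). The luminal median (0.0441) and mean (-0.0178), the leukocyte median (-0.00607) and mean (0.10), and the unfolded protein median (-0.00548) and mean (0.0287) differed in sign. With fry, the p53 (adjusted p = 3e-04), leukocyte (0.0036), mesenchymal (0.0074) and basal (0.04) lists passed. The interaction sets the both-cDNA arrays, on 1 side of the first component, against 3 groups on the other, and its count rose to 5607 without ESR1 array 1 and 5868 with array weights. The share above the sum depended on scaling, at 59.7%, and 72.7% of 3658 with arrays centred on their medians.

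**Figure D4:**
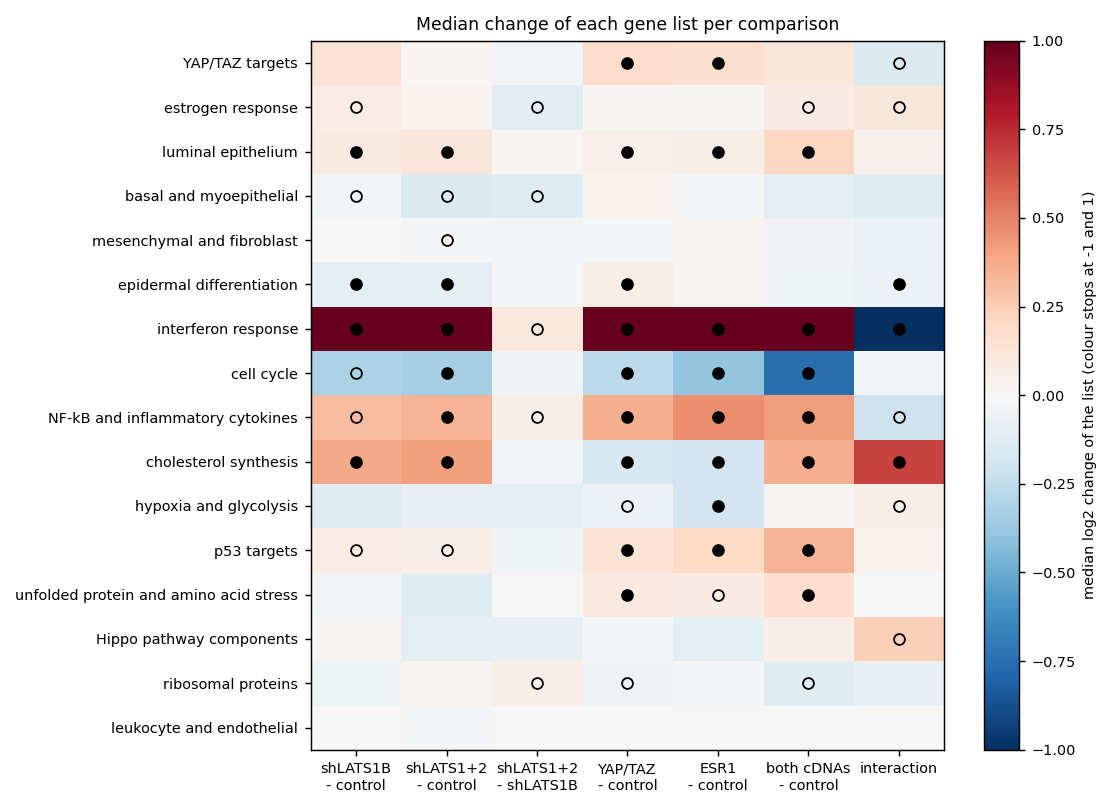
Median log2 change of each of the 16 gene lists (vertical axis) in the 7 comparisons (horizontal axis), with colour stopping at -1 and 1; circles mark lists with a camera adjusted p under 0.05, filled where the call held with an estimated correlation. The interferon list is raised in the 5 comparisons with the control arrays (medians 1.63 to 2.50), and the cholesterol list is lowered by each single cDNA (-0.16 and -0.20) and raised by both (0.36).

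The knockdown profiles were set beside the cDNA profiles across 18404 genes to ask how alike they were. With the profile of both cDNAs, the shLATS1B profile had r = 0.85 and that of the arrays labelled shLATS1+2 r = 0.785. With YAP/TAZ cDNA alone the values were 0.505 and 0.55, and with ESR1 cDNA alone 0.452 and 0.583. Unchanged groups simulated against the same control arrays gave 0.50, by construction and only where no gene changes. Values near it therefore do not mean that profiles with changed genes are unlike. Covariances were 0.0949 and 0.0882 with both cDNAs, 0.0281 and 0.0308 with YAP/TAZ and 0.035 and 0.0455 with ESR1, against 0.00322 in the simulation. The shLATS1B arrays shared 1779 higher and 1617 lower genes with both cDNAs, where independent lists would share 335.4 and 314, and 66 genes went in opposite directions. The arrays labelled shLATS1+2 shared 1532 and 1521, where independent lists would share 318.9 and 352.4, and 82 went in opposite directions. Genes called in all 5 groups against the control arrays numbered 331 higher and 378 lower. Part of each excess can come from the 3 shared control arrays, which were too few to split. The both-cDNA and knockdown arrays also lie on 1 side of the first component. A batch or culture difference cannot be told apart from their likeness. Without shared arrays, shLATS1B against both cDNAs minus YAP/TAZ had r = 0.758, Spearman's rho = 0.628 and 69.4% of genes of equal sign. For shLATS1+2 against both cDNAs minus ESR1 these were 0.442, 0.224 and 56.2%.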

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

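Of the tests in this part, the exchange of residuals between arrays, the count of genes and lists that part the 9 and 9 arrays, the profiles without shared arrays, the look for a batch or culture difference, and the choice of the glucocorticoid list came after the results had been seen. Each result here was picked out because both cDNAs together differed from the sum of each alone by a test of that difference (limma for genes, camera for lists), on arrays labelled YAP/TAZ cDNA in which YAP1 and WWTR1 were not raised.

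The interaction held for 3512 genes. Among 100 drawn splits of the 12 arrays into 4 groups, 1 split, the real one, gave as many, and the highest of the others gave 2755. The splits mix groups that differ, so those differences enter the spread within the drawn groups. They therefore do not test the sum and cannot exclude chance as the source of the count. With both single effects kept and the residuals exchanged between arrays, 1 of 100 draws, the real one, gave as many. The highest of the others gave 3040, while the real count was 2593 without array 3 with both cDNAs. This meets the prediction set against noise between single arrays, but by a narrow margin over that draw. A shift shared by all arrays of a group is not in the residuals, so the exchange cannot decide on it. The count was 5607 without ESR1 array 1. SLC6A14 (4.14), CYP24A1 (4.11), GPX2 (3.71), AKR1B10 (3.24) and KRT15 (3.20) lay above the sum on the log2 scale. SLC6A14 and CYP24A1 were dim in the control arrays, so their exact distance is not fixed. ID2 (-5.09), CCL20 (-4.67), RGS2 (-4.64), SCNN1G (-4.10) and SLC26A2 (-3.99) lay below it. Among targeted genes the values were 0.64 for LATS1, 0.37 for YAP1, 0.92 for WWTR1 and -0.65 for ESR1. The YAP1 call was lost without any of YAP/TAZ array 1, ESR1 array 2 or 3, or array 2 or 3 with both cDNAs (adjusted p from 0.051 to 0.063).

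The list medians were -1.14 for interferon, 0.68 for cholesterol synthesis, -0.0614 for epidermal, -0.15 for YAP/TAZ target, -0.21 for NF-kB, 0.0678 for hypoxia, 0.12 for estrogen response and 0.24 for Hippo genes. With an estimated correlation, 3 of these 8 calls held: interferon, cholesterol synthesis and epidermal. The sign of the interferon value rests on the control arrays: their mean lies 1.68 below the nearest other group, more than the distance from the sum, and a low state of these arrays stays open. For the YAP/TAZ target and NF-kB lists, the departure of the list mean also rests largely on the control arrays, whose means were the lowest of all groups. Beneath these means single members moved both ways from ESR1 cDNA to both cDNAs, 7 higher and 8 lower, and 9 and 5. The estrogen call was lost without control array 1 (adjusted p = 0.073) or YAP/TAZ array 1 (0.056), and the Hippo call without control array 1 (0.073), YAP/TAZ array 1 (0.059), ESR1 array 2 (0.096) or 3 (0.070), or array 3 with both cDNAs (0.075). Among brighter genes the estrogen (0.056), hypoxia (0.059) and Hippo (0.090) calls were lost, and the Hippo call also with quantile normalization (0.12) and fry (0.059).

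Of the 3512 genes, 922 (26.3%) share a pattern: every array with both cDNAs or a knockdown lies beyond every control, YAP/TAZ and ESR1 array. So do 434 of the 14892 other genes (2.91%). The division comes from the same data and a call for the interaction already sets both cDNAs apart from 3 of the groups, so the gap between these shares is a description and not a test. The pattern holds for 8 of the 10 genes named as furthest from the sum, not for GPX2 and AKR1B10. Of the 8 list means named above it holds for 1, cholesterol synthesis. SCNN1G, for example, had means of 5.29, 5.30 and 5.46 against 8.72, 8.91 and 9.19. Shared control arrays as the whole source are argued against by differences that share no array: both cDNAs minus YAP/TAZ cDNA and the arrays labelled shLATS1+2 minus the control arrays had r = 0.647 across genes, where r near 0 would follow. For these genes a batch or culture difference between the 2 sets of 9 arrays cannot be told apart from the groups, because the number of groups with arrays on both sides of the first component was 0 and the labels give no day. Such a difference alone cannot account for LATS1, which is lower in the knockdown arrays than with both cDNAs, or for the rise of interferon genes with either single cDNA. A shared effect of LATS1 knockdown and of both cDNAs also stays open and was not tested.

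A candidate explanation within this pattern is less glucocorticoid signalling in the 9 arrays, through the culture medium or through the cells. A list of 16 glucocorticoid receptor targets, 15 of them measured, was chosen because SCNN1G, ANGPTL4, DUSP1, MT1F and SERPINA3 led the pattern, and those 5 genes were left out. Its prediction was written before the members' values were seen. The list medians were -0.34 in the shLATS1B arrays, -0.39 in the arrays labelled shLATS1+2 and -0.319 with both cDNAs (camera with an estimated correlation, p = 0.012, 0.0078 and 0.016), against 0.067 with YAP/TAZ (camera p = 0.011, and 0.12 with an estimated correlation) and 0.0178 with ESR1 (0.21 and 0.42). Of the 15 genes, 2 were higher and 11 lower in each knockdown, and 1 higher and 10 lower with both cDNAs, with CEBPD higher in all 3. With YAP/TAZ 5 were higher and 0 lower, and with ESR1 5 and 3. TSC22D3, lower in both knockdowns, did not change with both cDNAs (-0.0625, limma adjusted p = 0.69). The list also kept MT1X and MT2A, of the same family as MT1F, so it is not independent of the genes that prompted it. The values meet the prediction within that limit and do not tell a change of medium from a response of the cells.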

How the results depend on the processing

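Of these alternatives, the fits without 2 arrays and with a covariate, and the profiles without shared arrays, were chosen after seeing the data. Of the values of named genes under alternatives, 7624 kept their direction and side of the threshold, 264 fell short of it, 5 newly passed and 4 reversed. Of list values, 1318 kept both, 68 fell short, 54 newly passed and 0 reversed. With the mean of a gene's probe sets, RPL13 reversed to -0.000869 (shLATS1B), 0.0359 (YAP/TAZ) and 0.0134 (ESR1), and RPS9 to -0.073 (shLATS1+2), which follows from averaging several probe sets. A further 1.5-fold threshold lowers counts by construction, to 926 (shLATS1B), 940 (shLATS1+2), 20 (between the knockdowns), 191 (YAP/TAZ), 446 (ESR1), 1335 (both cDNAs) and 1277 (interaction). The balance of higher and lower genes moved with scaling: with arrays centred on their medians the higher share was 47.4% (shLATS1B, against 51.8%), 37.7% (shLATS1+2, 47.6%), 40.6% (YAP/TAZ, 45.2%), 21.8% (ESR1, 37.1%), 48.2% (both cDNAs, 49.9%) and 72.7% (interaction, 59.7%). At 1.5-fold the majority turned to higher, at 56.1% (shLATS1+2), 70% (between the knockdowns, 44.1%), 76.4% (YAP/TAZ), 57.6% (ESR1) and 57% (both cDNAs). Between the knockdowns it was also 54% with the compared groups alone, 51.5% without shLATS1B array 2, 56.8% without shLATS1+2 array 3 and 60.4% without the 2 arrays. With all probe sets it was 51.8% for shLATS1+2, and with quantile normalization 48.9% for shLATS1B and 51.6% for both cDNAs. Array weights gave 248 genes between the knockdowns and 5868 for the interaction, and fitting the compared groups alone gave 1126 for ESR1. Without ESR1 array 1 and shLATS1+2 array 3, counts were 1945 (YAP/TAZ), 5776 (ESR1) and 5952 (interaction). With the within-group axis as a covariate they were 2773 (between the knockdowns), 2825 (YAP/TAZ), 5692 (ESR1) and 5820 (interaction). For these the cause was not tested. Lists called between the knockdowns numbered 3 with brighter genes, 3 without the 2 arrays, and 0 with an estimated correlation or fry. An estimated correlation gave 4 lists for shLATS1B and 3 for the interaction, and fry gave 15 for both cDNAs. The cause was not tested. Profiles that share no array had r = 0.758 and 0.624 (shLATS1B) and 0.647 and 0.442 (shLATS1+2) with both cDNAs minus YAP/TAZ or minus ESR1, where another reference group enters. Leaving out 1 array at a time gave 3588 to 4459 genes for shLATS1B, 3805 to 4078 for shLATS1+2, 33 to 54 between the knockdowns, 848 to 1246 for YAP/TAZ, 2299 to 5461 for ESR1, 4469 to 5522 for both cDNAs and 2593 to 5607 for the interaction. Those over 1.5 times apart from the full count were YAP/TAZ without its array 2 (848), ESR1 without its array 1 (5461) or 2 (2299), the interaction without ESR1 array 1 (5607), and the knockdowns without shLATS1B array 2 (33) or 3 (35) or shLATS1+2 array 3 (37, with 2 lists). Lists then numbered 9 to 9, 8 to 10, 2 to 7, 9 to 12, 9 to 9, 9 to 11 and 6 to 9 in the same order. With YAP/TAZ, ESR1 and both cDNAs, r ranged over 0.489 to 0.553, 0.371 to 0.492 and 0.838 to 0.862 for shLATS1B, and 0.526 to 0.576, 0.539 to 0.608 and 0.748 to 0.823 for shLATS1+2. With a replicate block the counts were 4254, 4370, 55, 1147, 3288, 5244 and 3311. Arrays of equal number did not shift in a common direction: they correlated with a median r of -0.0832 (-0.694 to 0.631), and 13 of 45 pairs exceeded 0.1. This does not show that the numbers carry no structure. On the within-group axis, array 1 had the opposite sign to arrays 2 and 3 in every group but shLATS1+2. Whether arrays numbered 1 were handled apart was not tested. Dim genes were taken to lie near the array background, which was not estimated and where small changes are hard to see.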

Other observations

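Of the tests in this part, those of an outlying control array, of a low state of the control arrays, of small RNA recovery, of the interferon state, of gene span and of NRF2 targets were chosen after the results had been seen, as were the fits without 2 arrays and with a covariate. The splits of arrays were planned.

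Each comparison of 3 with 3 arrays has 10 splits, too few for a share under 0.05, and in each 1 split, the real one, gave as many genes as the real one. The real counts were 4415 (shLATS1B), 4564 (shLATS1+2 by label), 59 (between the knockdowns), 1289 (YAP/TAZ by label) and 5414 (both cDNAs), with 0 in the highest other split of each. With ESR1 cDNA the real count was 3487 and the highest other 781.

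Interferon genes were higher in all 5 other groups than in the control arrays. A single outlying control array as the source is argued against: whichever was left out, the smallest list median over the 5 comparisons was at least 1.53, against 1.63 with all arrays. A low state of the control arrays, shared by all 3, may underlie the pattern: the 5 other group means spanned 0.552 times the gap of 1.68 from the control mean to the nearest of them. That test leaves a response to each hairpin and cDNA open as well, and the list also differed among these groups (ESR1 minus YAP/TAZ cDNA, median 0.37, adjusted p = 0.0032 with an estimated correlation).

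Arrays of 1 group differed along a common axis that held 46.7% of the variance within groups. ESR1 array 1 (-0.58) and shLATS1+2 array 3 (0.35) stood farthest out, with array weights of 0.213 and 0.43. The mean of 195 small RNAs, as deviations from group means, followed this axis over 18 arrays (Pearson's r = 0.96, permutation p = 2e-04, adjusted 4e-04; Spearman's rho = 0.938, p = 5e-04, adjusted 0.001; r = 0.933 without the 2 arrays farthest out). The deviations of the interferon list did not pass (r = 0.452, permutation p = 0.054; rho = 0.453, p = 0.084; r = 0.504 without 2 arrays), which decides nothing. These genes were part of the axis. With the axis made without them, r was 0.955 (p = 4e-04, adjusted 8e-04; rho = 0.928, p = 0.0017, adjusted 0.0034; r = 0.923 without 2 arrays) for small RNAs and 0.451 (p = 0.055; rho = 0.453, p = 0.093; r = 0.503 without 2 arrays) for interferon. Across 16897 protein-coding genes, which are not independent replicates, change along the axis had rho = -0.219 with the genomic span of the gene. A difference in RNA recovery between preparations is a candidate explanation for the axis, and 2 relations across arrays were tested.

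Between the knockdowns, AKR1B10, AKR1C1, AKR1C2, AKR1C3 and GPX2 raised the hypothesis of higher NRF2 target expression in the arrays labelled shLATS1+2. A list of 21 targets was reduced to 16 after its first result had been seen, because it held these 5 genes. Over the 15 measured of the 16 the median was 0.0524 (95% bootstrap interval -0.0144 to 0.157; camera p = 2e-05, and 0.047 with an estimated correlation), below the 0.1 that the hypothesis was set to need, and over the 20 measured with the 5 genes it was 0.135. Of the 15, 2 were higher (SLC7A11 and ABCC2) and 0 lower between the knockdowns. SLC7A11 had also been seen before, so the reduced list is not free of genes seen earlier. Against the control arrays 6 were higher and 5 lower in the arrays labelled shLATS1+2 (median 0.0477), which did not pass. AKR1B10 and GPX2 also lay far above the sum in the interaction, where 11 of the 15 were above and 0 below (median 0.383; p = 0.0081 with an estimated correlation). With both cDNAs 7 were higher and 0 lower (median 0.234), which passed with the preset correlation and not with an estimated one. The hypothesis stays open.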
